A study of Mus musculus with 20 samples.

How the data were processed

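Liver RNA of 20 male C57BL/6J mice was sequenced after an intravenous dose of an AAV8 vector, a virus that delivers genes to the liver, with the promoter of thyroxine binding globulin, which is active in hepatocytes. Per the submitters' series description, injection was at 8 weeks of age and a diet named HF/HS followed until 25 weeks. Per the labels' protocols, total RNA was extracted from frozen tissue and libraries came from a stranded total RNA kit. The 4 vectors, with 5 livers each, carried a short hairpin RNA against Pklr (shPKLR), a hairpin against firefly luciferase (shLUC, the control of the knockdown), the Pklr coding sequence (PKLR) or GFP (the control of the overexpression). Each library's group and replicate number came from its own labels, and each column of the deposited tables was matched to a library by its name, with 0 value columns left unmatched.

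The authors deposited 2 tables of whole-number read counts per gene, 1 per experiment, which are not normalized. HISAT2, DESeq2 and the mouse builds GRCm38 and mm10 are named in the submitters' processing notes, without versions. The counting program, the annotation release and the strand setting are not given in the sources used here. The knockdown counts list 27052 genes and the overexpression counts list 26286, with 25238 in both. Symbols and coordinates came from the GENCODE annotation of GRCm38; 26859 identifiers of the knockdown table and 26094 of the overexpression table matched. Counts of mitochondrial genes appear again at their nuclear copies: the copy Gm28661 held between 1.00 and 1.02 times the counts of mt-Co2 in the knockdown libraries. Reads that map to several places were thus counted more than once, and values of close paralogs (the Mup, Cyp2c, Cyp2d, Cyp3a, Acot and 7SK RNA families among those named) are uncertain.

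Library totals ran from 29933820 to 45413803 counts in 19 libraries and reached 167891680 in shPKLR replicate 4. Between 20957 and 25250 genes had a count in a library. At these depths genes under a few CPM are the least precise. Two-group tests used edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, after the filterByExpr rule and TMM normalization, on 15611 genes for knockdown and 15842 for overexpression. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Adjusted p-values in the text are from these fits unless another tool is named. The SE of a gene's log2 fold change is its size divided by the square root of the F statistic of the same test. It is thus not a separate measure of spread. CPM values are counts per 1e6 with TMM scaling. Log2 CPM values used for gene lists had a prior count of 2, while log2 fold changes of genes are from the edgeR fits. A model of all 20 livers and 16407 genes tested the overexpression effect less the knockdown effect (the difference) and the mean of both effects (the common effect). Pklr was also compared by an exact two-sided permutation test.

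For gene groups, 38 lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 35 lists with at least 3 tested members entered camera of limma 3.58.1 with a preset correlation of 0.01. An estimated correlation and fry, which asks whether the members of a list move on balance 1 way, were the alternatives. Adipocyte, skeletal muscle and pancreatic acinar markers had 2, 1 and 1 members past the filter in each experiment and were not tested. Chosen after seeing the data were list scores (the mean log2 CPM of the members in a liver, relative to the control mean) with exact permutation tests, and list tests in the model of all livers. For the scores, labels were permuted within each experiment when both were combined.

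The genes named were a panel of glycolytic, lipogenic and other liver genes including Pklr, the 6 largest changes in each direction among called genes with a mean of at least 2 CPM, up to 2 members with the smallest p from each list called by camera, and up to 2 called members of any other list with at least 3 calls. Predicted genes were passed over for the largest changes. In the joint model the 5 smallest p among calls were named. Other genes are said to be chosen after their values were seen.

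The alternatives were RLE size factors, no filter on low counts, a filter of over 1 CPM in at least 5 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, mitochondrial and ribosomal RNA genes left out, 1 fit of all 20 libraries, and each library left out in turn. The steps were tested on simulated counts with the means, spreads and library sizes of the real genes. In the simulated knockdown, with 15427 genes tested, 63.1% of 65 genes changed 2-fold and 96.9% of 65 changed 4-fold were called; for overexpression, with 15675 genes, these shares were 77.3% of 66 and 98.5% of 66. In simulations of the difference, 45.5% of 66 genes changed 2-fold were called among 16233, and for the common effect 86.2% of 65 among 16245. Unchanged genes made up 10 of 131 calls in the simulated knockdown and 11 of 160 in the overexpression. For the difference they made up 10 of 115 calls and for the common effect 9 of 183. A list shifted 1.5-fold was called by camera and fry in both simulated experiments, with 0 other lists called. Each simulated gene was drawn independently, so this does not give the rate of false lists where genes vary together. In other splits of the real livers, described below, camera called a median of 10 lists in the knockdown and 13 in the overexpression.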

Results

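The data are read counts per gene from 20 mouse livers in 2 experiments on Pklr, which encodes the liver and red cell pyruvate kinase, the enzyme of the last step of glycolysis. One experiment compared 5 livers given a hairpin against Pklr (shPKLR) with 5 given a luciferase hairpin (shLUC). The other compared 5 livers given Pklr (PKLR) with 5 given GFP. The series concerns the part Pklr plays in fatty liver disease, and all mice received the diet labelled HF/HS. Library totals ran from 29933820 to 45413803 counts, except 167891680 for shPKLR replicate 4. Mitochondrially encoded genes took 7.79% to 10.98% of the counts.

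Pklr (ENSMUSG00000041237; GRCm38 chromosome 3, 89136142 to 89146784) followed the vectors in every liver. It was at 465 ± 112 CPM (SD, n = 5) with shLUC and 52.95 ± 22.5 CPM (SD, n = 5) with shPKLR, which is 11.4% of the control mean. With GFP it was at 122 ± 35.3 CPM (SD, n = 5) and with PKLR at 772 ± 220 CPM (SD, n = 5), or 6.34 times the control mean. The log2 fold changes were -3.13 (SE 0.30, edgeR adjusted p = 0.0027) and 2.67 (SE 0.28, edgeR adjusted p = 0.0023). In both experiments the groups did not overlap, and the exact two-sided permutation p was 0.00794, the smallest that 5 against 5 can give. Pkm, the other pyruvate kinase gene, was at 11.6 ± 1.14 CPM with shLUC and 13.3 ± 2.04 CPM with shPKLR (SD, n = 5 each; adjusted p = 0.45).

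**Figure D1:**
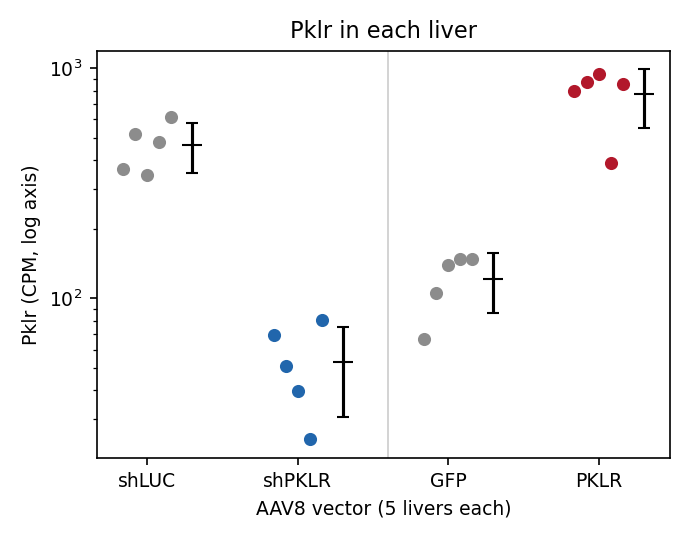
Pklr in CPM (log axis) in each of the 20 livers by vector, with the mean and SD of the 5 livers as a bar beside the points. The shPKLR livers lie between 24.4 and 80.5 CPM, below all shLUC livers, and the PKLR livers between 389 and 945 CPM, above all GFP livers.

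The knockdown comparison asked which liver transcripts differ when Pklr is reduced. Genes of cholesterol synthesis and of de novo lipogenesis were lower in shPKLR livers as groups. All 25 tested cholesterol genes had negative log2 fold changes, with a median of -0.99, and 24 of them fell when p was adjusted over the list alone. Among them Insig1, a sterol-regulated brake on cholesterol synthesis, went from 419 ± 77.2 to 195 ± 24.3 CPM (SD, n = 5 each; log2 fold change -1.10, SE 0.15), and Dhcr7, the last enzyme of 1 branch of the pathway, had a log2 fold change of -0.98 (SE 0.18). All 19 lipogenic genes were lower too, with a median of -1.13, and 16 fell adjusted over the list alone. Fasn, the fatty acid synthase, was at 1376 ± 649 CPM with shLUC and 402 ± 146 CPM with shPKLR (SD, n = 5 each; log2 fold change -1.78, SE 0.36).

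Over all 15611 genes tested, edgeR called only Pklr, so no member of either list passed there; Acacb and Insig1 stood just over the threshold, both at an adjusted p of 0.0509. Other lipogenic genes had log2 fold changes of -1.63 (SE 0.24) for the acetyl-CoA carboxylase gene Acacb and -1.10 (SE 0.27) for Acaca. They were -1.44 (SE 0.38) for the ATP citrate lyase gene Acly, -1.45 (SE 0.37) for the desaturase gene Scd1, -1.56 (SE 0.38) for the elongase gene Elovl6 and -1.61 (SE 0.31) for the acetyl-CoA synthetase gene Acss2. The transcription factor genes Srebf1 (-0.24, SE 0.27) and Mlxipl (0.43, SE 0.26), which drive lipogenic genes, had adjusted p-values of 0.66 and 0.41. Both lists passed camera (adjusted p = 1.7e-24 for cholesterol synthesis and 3.5e-16 for lipogenesis). With an estimated correlation neither did (adjusted p = 0.195 for each), while fry held both, at adjusted p = 0.020 and 0.021. Fry held each in 5 of 10 fits with 1 library left out; with the replicate number as a block its adjusted p was 0.040 for cholesterol synthesis and 0.071 for lipogenesis. In score, all 5 shPKLR livers lay below every shLUC liver for both lists.

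Camera called 8 further lists in the knockdown, and each call was lost with an estimated correlation and with fry. Of the 27 genes of pyruvate handling and the TCA cycle 25 were lower (median log2 fold change -0.24, camera adjusted p = 1.3e-06, adjusted p = 0.66 with an estimated correlation), and 4 fell adjusted over the list alone, among them Cs, citrate synthase (-0.61, SE 0.14), and Pdk1, a pyruvate dehydrogenase kinase (-0.78, SE 0.18). The 11 genes associated with the carbohydrate-responsive factor ChREBP had a median of -0.29 with 1 fall adjusted over the list alone, in Pnpla3, a lipid droplet lipase and transacylase (-2.59, SE 0.65); Slc2a2, a glucose transporter, was at -0.49 (SE 0.19). Mitochondrially encoded genes (12 of 15 lower, median -0.18), with mt-Nd4l at -0.62 (SE 0.19) and mt-Rnr1 at 0.65 (SE 0.24), had none past either adjustment. Fatty acid oxidation genes (26 of 34 lower, median -0.09) held 1 fall adjusted over the list alone, in Cyp4a10 (-0.84, SE 0.16), with Eci2 at 0.34 (SE 0.14). Of 23 lipid droplet genes, 1 rose and 3 fell adjusted over the list alone: Lpl, lipoprotein lipase, rose (1.15, SE 0.23) and Mogat1, a monoacylglycerol acyltransferase, was among the falls (-1.23, SE 0.31). Amino acid catabolism genes (17 of 21 lower, median -0.16) included Gpt2 (-0.58, SE 0.18) and Got1 (-0.62, SE 0.29), with none past either adjustment. For these 5 lists the adjusted p with an estimated correlation was 0.78, or 0.83 for fatty acid oxidation. Of 10 fits with 1 library left out, camera held the ChREBP list in 6, mitochondrially encoded genes in 4, lipid droplets in 5, amino acid catabolism in 7 and fatty acid oxidation in 6 (median -0.03, adjusted p = 0.17 without shPKLR replicate 4). Without shPKLR replicate 5 the medians of mitochondrially encoded and amino acid catabolism genes were -0.10 and -0.09. With the replicate number as a block, camera lost the ChREBP list (adjusted p = 0.052) and the lipid droplet list (adjusted p = 0.061).

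The 2 lists called upward were interferon response genes and macrophage markers. Of 34 interferon genes 32 were higher (median log2 fold change 0.48, camera adjusted p = 9.6e-06, adjusted p = 0.78 with an estimated correlation), and 9 rose adjusted over the list alone, among them Mx1 (1.49, SE 0.38) and Oas2 (1.66, SE 0.46). Of 25 macrophage and antigen presentation genes 24 were higher (median 0.42, camera adjusted p = 0.0012, adjusted p = 0.78 with an estimated correlation), none past either adjustment, with Marco at 1.77 (SE 0.53) and Itgax at 0.80 (SE 0.29). The lowest medians of both lists with 1 library left out, 0.35 and 0.33, came without shPKLR replicate 4, whose estimated sample weight was 0.136; that of shPKLR replicate 1 was 0.471. Markers of other cell types were not called: medians were 0.21 for extracellular matrix and stellate cells, 0.39 for lymphocytes, 0.77 for neutrophils (4 genes; past camera and fry with the replicate number as a block, adjusted p = 0.012 and 0.040), -0.03 for endothelial cells, 0.18 for cholangiocytes and -0.80 for erythroid cells. Single libraries moved these medians: to 0.08 (matrix) and 0.06 (cholangiocytes) without shPKLR replicate 1, to 0.14 (lymphocytes), 0.52 (neutrophils) and -0.14 (endothelial) without shPKLR replicate 4, to 0.63 (lymphocytes) without shPKLR replicate 2, to 0.07 (endothelial) without shPKLR replicate 5 and to -0.34 (erythroid) without shLUC replicate 3.

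Further panel genes in the knockdown did not pass. The gluconeogenic gene Pck1 had a log2 fold change of 0.76 (SE 0.22) and the fatty acid transporter gene Cd36 one of -1.01 (SE 0.31). G6pc (0.02, SE 0.20), Cpt1a (-0.07, SE 0.24), Ppara (-0.29, SE 0.37), Plin2 (-0.09, SE 0.21), Cidec (0.61, SE 0.52), Col1a1 (0.51, SE 0.28) and Txnip (0.22, SE 0.16) lay closer to their spread, and Timp1 was below the count filter. The count of 1 called gene depended on the method: DESeq2 called 260 genes, the fit of all 20 libraries 114, and limma-voom 8, and 2339 genes had an unadjusted p under 0.05. It was 12 without shPKLR replicate 2, 6 without shPKLR replicate 1 or 3 and 3 without shLUC replicate 1. It was 1 without shPKLR replicate 4, the deepest library, and 7 with that library thinned to the depth of the others.

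The overexpression comparison asked which transcripts differ when Pklr is raised. edgeR called 322 of 15842 genes, of which 188 rose and 134 fell. Genes of lipogenesis and cholesterol synthesis rose: 8 of 19 lipogenic genes (11 adjusted over the list alone) and 8 of 25 cholesterol genes (20 adjusted over the list alone), with 0 falls in either. Acaca rose from 89.0 ± 8.80 to 168.2 ± 36.3 CPM (SD, n = 5 each; log2 fold change 0.92, SE 0.14, adjusted p = 0.0089), Fasn from 411 ± 119 to 957 ± 222 CPM (1.22, SE 0.23, adjusted p = 0.026) and Acly from 160 ± 37.6 to 482 ± 207 CPM (1.59, SE 0.26, adjusted p = 0.018). Mvd, an enzyme of the mevalonate pathway, rose from 7.02 ± 2.86 to 23.9 ± 5.26 CPM (1.77, SE 0.25).

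Both lists passed camera (adjusted p = 9.4e-16 for cholesterol synthesis and 1.2e-08 for lipogenesis) and fry (adjusted p = 0.042 for each), not camera with an estimated correlation (adjusted p = 0.588 for each). Fry held each in 1 of 10 fits with 1 library left out, and with the replicate number as a block its adjusted p was 0.108 and 0.112. In score all 5 PKLR livers lay above every GFP liver for both lists. Scd1 (-0.12, SE 0.40), Srebf1 (0.25, SE 0.30), Mlxipl (0.37, SE 0.26) and Elovl6 (0.46, SE 0.19) did not pass. Markers of pericentral hepatocytes, the cells around the central vein, were the third list held by fry (adjusted p = 0.042; camera adjusted p = 1.1e-05, adjusted p = 0.588 with an estimated correlation), in 2 of 10 fits with 1 library left out and not with the block (adjusted p = 0.108). Of 15 genes 14 were higher and 2 rose (3 adjusted over the list alone): Glul, glutamine synthetase, from 615 ± 26.5 to 1047 ± 130 CPM (0.77, SE 0.10, adjusted p = 0.0055) and Nkd1, a Wnt pathway gene (0.61, SE 0.13, adjusted p = 0.033).

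**Figure D2:**
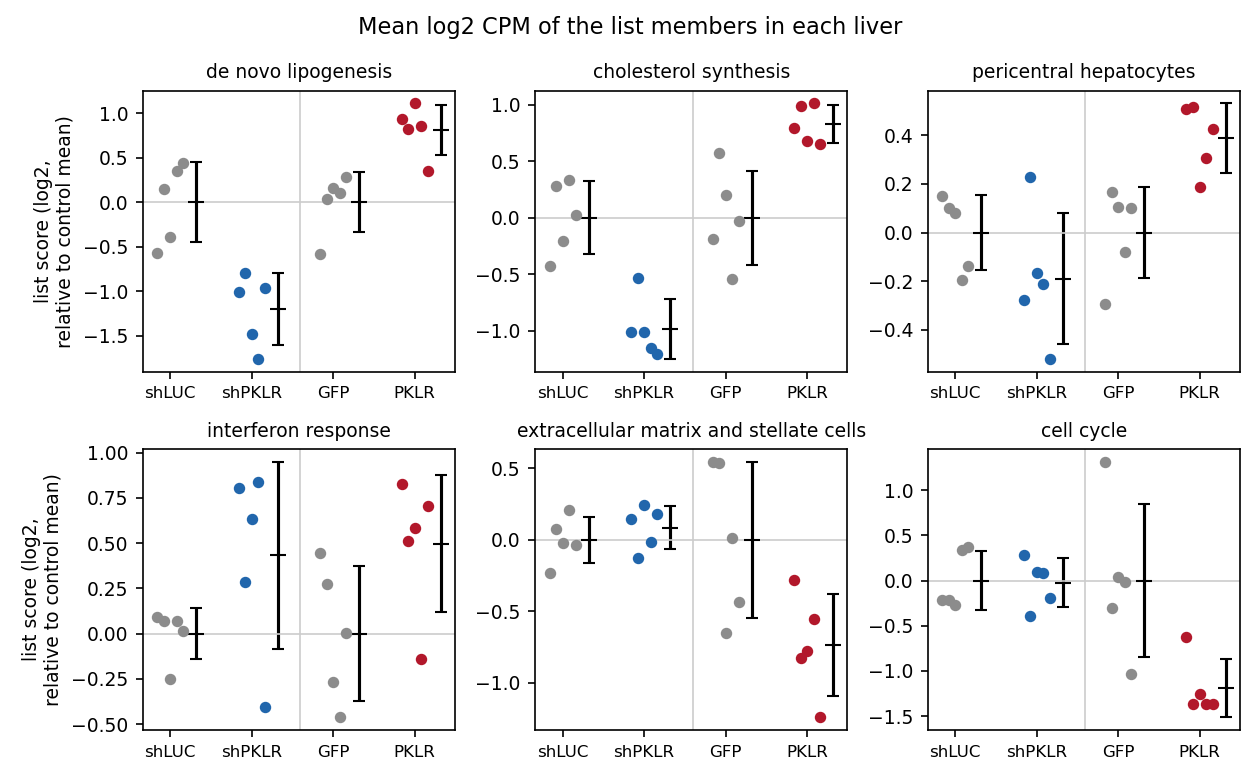
Scores of 6 gene lists in each liver: the mean log2 CPM of the list members, relative to the control mean of the same experiment, with the mean and SD of 5 livers beside the points. Lipogenesis and cholesterol scores of all shPKLR livers lie below, and of all PKLR livers above, their controls; GFP replicate 1 has the highest cell cycle score, 1.32.

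Among called genes of at least 2 CPM, the largest rises were in Chrna4, a nicotinic acetylcholine receptor subunit (2.91, SE 0.53), Pnpla3 (2.75, SE 0.34), the G protein subunit gene Gna14 (2.68, SE 0.23), Pklr itself (2.67, SE 0.28), the cytochrome P450 gene Cyp2c37 (2.16, SE 0.33) and the cholesterol hydroxylase gene Cyp46a1 (2.15, SE 0.47). The largest falls were in Gpnmb, a glycoprotein of lipid-laden macrophages (-3.55, SE 0.75), the 7SK RNA gene Rn7sk (-3.44, SE 0.57), the tubulin gene Tuba8 (-2.41, SE 0.28), the clock-regulated gene Noct (-2.30, SE 0.20), asparagine synthetase, Asns (-2.21, SE 0.44), and Cdc42ep5, an effector of the GTPase Cdc42 (-2.16, SE 0.16). Cdc42ep5 (ENSMUSG00000063838; chromosome 7, 4151260 to 4164860) had the smallest adjusted p, 0.00011, and went from 9.24 ± 1.89 to 2.06 ± 0.20 CPM (SD, n = 5 each).

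Camera called 19 lists in the overexpression, 11 up and 8 down. Apart from the 3 above, none was held by fry, and no call was held with an estimated correlation, where adjusted p-values ran from 0.588 to 0.819. Among the metabolic lists, 3 of 11 ChREBP-associated genes rose (5 up and 1 down adjusted over the list alone), with Pnpla3 and the triokinase gene Tkfc (0.86, SE 0.16) among them, and 3 of 27 pyruvate and TCA cycle genes rose (4 up and 1 down adjusted over the list alone), with Pdk1 (0.93, SE 0.18) and Cs (0.48, SE 0.10). Mitochondrially encoded genes (13 of 15 higher, median 0.25; mt-Nd4l 0.46, SE 0.13; mt-Nd5 0.41, SE 0.14) and nuclear respiratory chain genes (54 of 75 higher, median 0.06; Cycs 0.21, SE 0.08; Ndufa8 0.20, SE 0.08) had no member past either adjustment. Without GFP replicate 1 the respiratory chain median was 0.0035 (camera adjusted p = 0.80), and camera held this list in 5 of 10 fits with 1 library left out. Fatty acid oxidation genes were mostly lower (26 of 34, median -0.10); Acot1, an acyl-CoA thioesterase, fell (-1.64, SE 0.35, adjusted p = 0.047), and Pdk4 was at -1.79 (SE 0.53). Without PKLR replicate 2 the fatty acid oxidation median was -0.05 (camera adjusted p = 0.084).

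Periportal genes, the counterpart of the pericentral list, had a median of -0.46; 1 of 11 fell, the aldehyde dehydrogenase gene Aldh1b1 (-1.32, SE 0.21, adjusted p = 0.015), and 8 fell adjusted over the list alone, with Gls2, liver glutaminase, at -0.60 (SE 0.15). Of 21 amino acid catabolism genes none passed over all genes (1 rise and 4 falls adjusted over the list alone), with Sdsl at -0.62 (SE 0.15). Xenobiotic genes (median 0.51) held 2 rises and 2 falls, or 8 and 3 adjusted over the list alone; Cyp2c37 rose and Cyp2c55 fell (-0.82, SE 0.15). Male-biased liver genes (median 0.62) held 1 rise, Cyp2d9 (1.17, SE 0.26), or 4 adjusted over the list alone, with the urinary protein gene Mup7 at 3.31 (SE 0.87, adjusted p = 0.086). Female-biased genes (median -0.27) held 1 fall, Cyp3a44 (-1.61, SE 0.35), or 1 rise and 3 falls adjusted over the list alone, with Cyp3a41a at -1.98 (SE 0.53). Clock genes (median 0.33) held no call, or 4 up and 1 down adjusted over the list alone; Bhlhe40 was at 0.70 (SE 0.20). With 1 library left out, camera held amino acid catabolism in 5 of 10 fits, xenobiotic genes in 6, and the male-biased, female-biased and clock lists in 8 each. Without PKLR replicate 5 the male-biased and female-biased medians were 0.39 and -0.18, and without GFP replicate 3 the amino acid catabolism median was -0.04. In the redox and pentose phosphate list, which camera did not call, the transketolase gene Tkt rose (0.55, SE 0.11) and the glutathione transferase gene Gstm3 fell (-1.85, SE 0.36).

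Of 34 interferon response genes 5 rose (20 adjusted over the list alone; median 0.58, camera adjusted p = 8.0e-09), among them Oasl1 (1.07, SE 0.19, adjusted p = 0.019) and Ifih1, a sensor of viral RNA (0.64, SE 0.13, adjusted p = 0.026). With an estimated correlation the adjusted p of the interferon list was 0.588, as it was for the matrix and cell cycle lists below. Lists of other cells and of division were lower in PKLR livers. Of 31 extracellular matrix and stellate cell genes 29 were lower (median -0.86, camera adjusted p = 2.0e-10); Thbs2, a thrombospondin, fell (-1.13, SE 0.24), and 19 fell adjusted over the list alone, with Reln at -0.79 (SE 0.19). Of 26 cell cycle genes 22 were lower (median -1.74, camera adjusted p = 8.2e-08); Birc5, a mitotic survival gene, fell from 3.95 ± 3.03 to 0.92 ± 0.28 CPM (SD, n = 5 each; adjusted p = 0.049993), and 18 fell adjusted over the list alone, with the cyclin gene Ccnb2 at -2.88 (SE 0.65). Of 25 macrophage genes 20 were lower (median -0.50); Gpnmb fell, 8 fell adjusted over the list alone, and Trem2 was at -1.71 (SE 0.47). The macrophage call ended without GFP replicate 1 (median -0.23, camera adjusted p = 0.090) and without PKLR replicate 4 (median -0.35, camera adjusted p = 0.077). Without GFP replicate 1 the cell cycle median was -0.94. Lymphocyte genes (median -0.45) held 1 fall, the antibody gene Igkc (-0.74, SE 0.16), or 2 adjusted over the list alone, with Gzma at -1.23 (SE 0.36); camera held this list in 7 of 10 fits with 1 library left out, and its median was -0.24 without PKLR replicate 4.

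Endothelial (0.04), cholangiocyte (-0.06), neutrophil (-0.39) and erythroid (-0.48) medians belonged to lists that camera did not call. The neutrophil median was -0.10 without GFP replicate 1 and the erythroid median -0.24 without GFP replicate 3; with 1 library left out the endothelial median ran from -0.09 (without PKLR replicate 3) to 0.14 (without PKLR replicate 4) and the cholangiocyte median from -0.15 (without PKLR replicate 4) to 0.07 (without GFP replicate 2). GFP replicate 1 stood apart from the other GFP livers in several of these lists: its scores were 1.32 for cell cycle, 0.94 for macrophages, 0.54 for matrix genes and -0.58 for lipogenesis, and its estimated sample weight was 0.377. Further panel genes that did not pass were Pck1 (-0.82, SE 0.29), G6pc (-0.43, SE 0.23), Cpt1a (-0.34, SE 0.14), Ppara (0.11, SE 0.15), Plin2 (-0.31, SE 0.19), Cidec (-1.48, SE 0.66), Cd36 (0.04, SE 0.44), Col1a1 (-1.25, SE 0.47), Timp1 (-1.90, SE 0.71), Txnip (-0.41, SE 0.15) and Pkm (-0.58, SE 0.24). The count of 322 called genes was 1107 with DESeq2. It was 176, 174 and 128 without GFP replicates 1, 2 and 4, and 202, 187, 139, 213 and 172 without PKLR replicates 1 to 5.

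The difference between the experiments asked which genes responded in opposite or unequal ways to gain and loss of Pklr. Each effect is relative to its own control, and the controls differed in level. Fasn was at 1376 CPM with shLUC and 402 with shPKLR, and at 411 with GFP and 957 with PKLR. In the model of all 20 livers, 902 of 16407 genes differed, 451 higher and 451 lower in overexpression than in knockdown. The contrast favours opposite signs, which 897 of the 902 had; 515 had them with an unadjusted p under 0.05 in both experiments. The count of 902 was 485 and 600 without shLUC replicates 2 and 5, 1384 without shPKLR replicate 2, 517 and 588 without GFP replicates 1 and 4, and 577 without PKLR replicate 3. After Pklr (difference 5.77, SE 0.43) the smallest p-values belonged to Tuba8 (-4.04, SE 0.45), the steroid dehydrogenase gene Hsd17b6 (-2.74, SE 0.32), Acacb (2.69, SE 0.33) and the unnamed transcript 4732465J04Rik (-1.03, SE 0.13). Their edgeR adjusted p-values ran from 0.00012 to 0.00028. Tuba8 had fitted log2 fold changes of 1.62 (SE 0.32) under knockdown and -2.42 (SE 0.32) under overexpression, Hsd17b6 of 1.58 (SE 0.23) and -1.16 (SE 0.23), and Acacb of -1.62 (SE 0.24) and 1.07 (SE 0.23). In this model all 3 passed in both experiments, with adjusted p-values of 0.029 and 0.0010 for Tuba8, 0.0049 and 0.016 for Hsd17b6, and 0.0049 and 0.021 for Acacb.

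Of the 25 cholesterol synthesis genes 22 differed, all higher under overexpression, as did 14 of the 19 lipogenic genes. The difference passed fry for 5 lists: cholesterol synthesis (median 1.77, adjusted p = 0.00022), lipogenesis (median 1.99, adjusted p = 0.00024), pyruvate and TCA cycle (0.30, adjusted p = 0.025), ChREBP-associated genes (0.33, adjusted p = 0.040) and pericentral hepatocytes (0.54, adjusted p = 0.040). With camera and an estimated correlation the lowest adjusted p was 0.071, for cholesterol synthesis and lipogenesis. The exact permutation test of list scores gave p = 3.1e-05 for both of these lists, the smallest it can give, and an adjusted p of 0.00055 over 35 lists. It also held TCA cycle (adjusted p = 0.0044), ChREBP-associated (0.0083), pericentral and xenobiotic genes (0.032 each). These list tests on the difference were chosen after seeing the data. Lists can share members: Pnpla3 is in both the ChREBP-associated and the lipogenesis list, so their results are not independent.

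Across the 15444 genes tested in both experiments, Pklr left out, the log2 fold changes had a Pearson r of -0.33 and a Spearman rho of -0.35; genes are not independent replicates, and regrouping the livers gave p = 0.07 for r and 0.04 for rho (100 groupings). Pklr, the target of both vectors, was the only gene called in both separate fits, against 0.012 expected from independent lists with opposite signs. At an unadjusted p under 0.05, a threshold chosen after seeing the data, 607 genes passed in both with opposite signs and 55 with the same sign, against 212 and 218 from independent lists. Of the 309 genes called in overexpression and tested in knockdown (Pklr left out), 248 had the opposite sign in knockdown, or 80.3%. An unadjusted knockdown p under 0.05 was reached by 102 of them and by 5 genes with the same sign. The share of opposite signs over all genes was not counted.

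**Figure D3:**
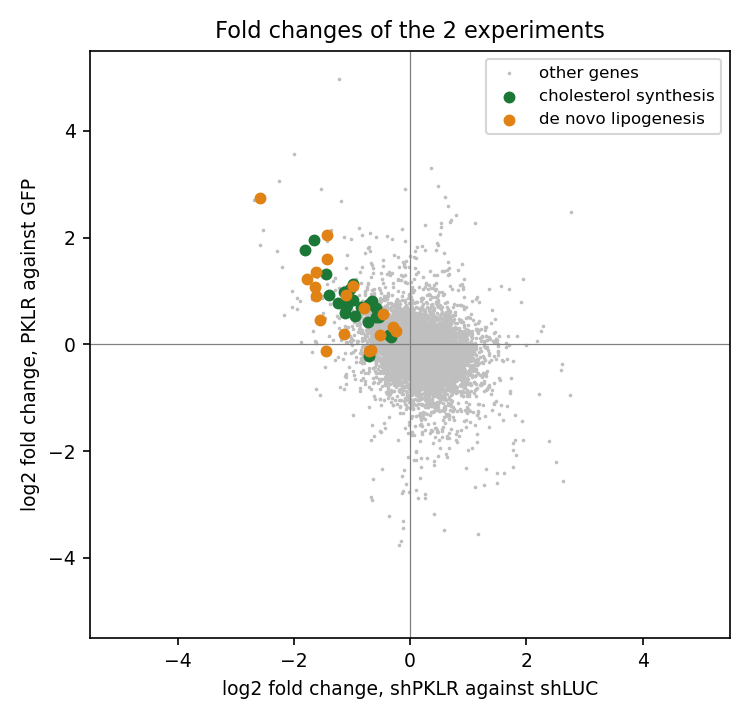
Log2 fold change of each of the 15444 genes tested in both experiments, Pklr left out, under knockdown (x axis) and overexpression (y axis), with 2 gene lists in colour. All cholesterol synthesis and lipogenesis genes lie left of 0 on the knockdown axis, and most lie above 0 on the overexpression axis.

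For the common effect, the mean of both effects, which 1 experiment alone can drive, edgeR called 0 of 16407 genes, with 1561 at an unadjusted p under 0.05; DESeq2 called 51 and limma-voom 0. The smallest edgeR adjusted p was 0.074, for Cdc42ep5, whose fitted log2 fold changes were 0.09 (SE 0.24) under knockdown and -2.18 (SE 0.25) under overexpression. The magnesium transporter gene Slc41a1 was higher in both, by 0.77 (SE 0.19) and 0.74 (SE 0.19), with an adjusted p of 0.092 for the common effect; both genes were chosen after their values were seen.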

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

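The tests in this part were chosen after the results they bear on had been seen, except the splits for the fry lists in the model of all livers, whose bound was set before those splits were run. Of 228 groups of 5 values examined for a liver far from the other 4, 12 stood out, where chance gives about 1 in 20. Library totals, in units of 1e6 counts, were 167.9 for shPKLR replicate 4, against 29.9 to 35.6 in the other shPKLR libraries, and 45.4 for shLUC replicate 5, against 31.8 to 34.2. In the knockdown, Pck1 was at 773 CPM in shPKLR replicate 1 (others 1411 to 1797), Cd36 at 15.2 CPM in shPKLR replicate 4 (others 49.5 to 69.9) and Got1 at 108 CPM in shLUC replicate 1 (others 167 to 199). In the overexpression, Pklr was at 389 CPM in PKLR replicate 4 (others 801 to 945), Mlxipl at 507 CPM in PKLR replicate 2 (others 230 to 285), and PKLR replicate 1 held Acot1 at 25.8 CPM (others 13.1 to 15.6) and Ccnb2 at 0.97 CPM (others 0.37 to 0.46). GFP replicate 1 stood apart in Srebf1 (71.2 CPM, others 198 to 284), Acot1 (107 CPM, others 33.3 to 41.5) and Bhlhe40 (22.8 CPM, others 45.6 to 52.0).

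The matrix and cell cycle lists were lower in PKLR than in GFP livers, with GFP replicate 1 at the high end of both, at an adjusted p of 0.588 each with an estimated correlation and of 0.072 (cell cycle) and 0.097 (matrix) at the lowest with fry over 10 fits with 1 library left out. Without it the median log2 fold change of the cell cycle list was -0.94 instead of -1.74 (camera adjusted p = 2.6e-08), with a score difference of -0.86 (SE 0.29, exact permutation p = 0.024), so that liver is not the whole of this list's pattern. For the matrix list the median was -0.75 instead of -0.86 (camera adjusted p = 1.7e-08) and the score difference -0.60 instead of -0.74 (SE 0.31, exact permutation p = 0.087 without it), so most of the difference stayed, though not past the spread between livers by this test. If a lower share of hepatocytes in GFP livers raised the markers of every other cell type alike, matrix and endothelial scores would move together. The matrix score less the endothelial score was -0.69 (SE 0.27) in PKLR against GFP livers (exact permutation p = 0.048). This p is not adjusted, includes GFP replicate 1 and rests on the endothelial list alone, so a shift in cell shares is not excluded. Also open is a change in the stellate, macrophage and dividing cells themselves, which may follow Pklr. A difference between the vectors' control livers is open too, and the design does not separate these.

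Splits of the 10 livers of an experiment into other groups of 5, 100 in all with the real one, show how far chance can be excluded. For overexpression 1 of 100 splits gave 322 called genes or more, the real one, and the highest of the others was 14. That is the smallest share 100 splits can give, so chance is made less likely for that count and is not excluded. The 1 gene called in the knockdown is the hairpin's own target, so its splits (2 of 100 with at least 1 gene, highest other 3) say only that the target was lowered. The camera counts do not exclude chance: 56 of 100 splits gave 10 or more lists in the knockdown (highest other 21), and 13 of 100 gave 19 or more in the overexpression (highest other 22). With fry, 1 of 100 splits gave the 2 knockdown lists (highest other 1) and 3 of 100 gave the 3 overexpression lists (highest other 9). Such counts were rare among the splits. These shares are not adjusted over the counts tested, so chance is made less likely and is not excluded.

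In the model of all livers, with labels regrouped within each experiment, 1 of 100 splits gave 902 differing genes or more, with a highest other of 3, and 2 of 100 gave the 5 differing fry lists, with a highest other of 6. For the common effect the real counts were 0 genes and 0 fry lists, which all 100 splits must reach (highest others 24 and 3), so the splits decide nothing there. For the correlation of fold changes 7 of 100 splits were as far from 0 as -0.33 (highest other 0.461). For the rank correlation of -0.35 it was 4 of 100 (highest other 0.447). These are 2 measures of 1 pattern on the same splits, and together they do not exclude chance. The 606 opposite genes at an unadjusted p under 0.05, Pklr left out, were reached in 1 of 100 splits, with a highest other of 349. The 1 gene in both call lists (1 of 100 splits, highest other 0) is Pklr, the target of both vectors, so its splits say nothing of shared responses.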

How the results depend on the processing

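Pklr kept its direction and its call under every setting run, with leave-one-out log2 fold changes from -3.33 to -2.95 (knockdown) and 2.51 to 2.84 (overexpression). The count of genes changed by knockdown, 1 as reported, was 7 with RLE size factors, 17 with no filter, 260 with DESeq2, 8 with limma-voom, 11 at an adjusted p of 0.1, 114 in 1 fit of all 20 libraries, and 7 without mitochondrial and ribosomal RNA genes. Alternatives chosen after seeing the data gave 7 without nuclear mitochondrial copies and Mup genes, 9 with limma-voom sample weights and 7 with shPKLR replicate 4 thinned. Leaving out 1 library gave 1 to 12 genes (12 without shPKLR replicate 2, 6 without shPKLR replicate 1 or 3, 3 without shLUC replicate 1). The 322 genes changed by overexpression became 1107 with DESeq2 (533 up, 574 down, against 188 and 134) and 779 at an adjusted p of 0.1, and 128 to 469 with 1 library left out: 128 without GFP replicate 4, 174 and 176 without GFP replicates 2 and 1, and 202, 187, 139, 213 and 172 without PKLR replicates 1 to 5. The 902 differing genes became 1614 with DESeq2, 2027 at an adjusted p of 0.1, and 485 to 1384 with 1 library left out (485 and 600 without shLUC replicates 2 and 5, 1384 without shPKLR replicate 2, 517 and 588 without GFP replicates 1 and 4, 577 without PKLR replicate 3). The 0 common genes became 51 with DESeq2, 1 with no filter, 2 at an adjusted p of 0.1, and 0 to 14 with 1 library left out (14 and 5 without shPKLR replicates 5 and 3, 4 without GFP replicate 3 or 4, 2 without PKLR replicate 4, 1 without shLUC replicate 2 or GFP replicate 5). Genes called in both experiments, 1 as reported, were 85 with DESeq2, 6 at an adjusted p of 0.1, 662 at an unadjusted p under 0.05 and 1 to 4 with 1 library left out (4 without shPKLR replicate 2, 2 without shLUC replicate 1). The correlation of fold changes was -0.67 over genes called in either experiment, a set chosen by the fold changes themselves, and -0.38 to -0.26 with 1 library left out. The 10 lists changed by knockdown became 0 with an estimated correlation, 2 with fry, 6 under the stricter filter and 0 by exact permutation of scores, and 7 to 13 with 1 library left out; the 19 under overexpression became 0, 3 and 0 by the first, second and last of these, and 12 to 22 with 1 library left out (12 without PKLR replicate 2). The exact permutation test has little room here, since its smallest p with 5 against 5 livers is 0.00794. The lipogenesis and cholesterol lists were at that p in both experiments, with a permutation p of 0.093 after adjustment over the lists. With 1 library left out, fry held the lipogenesis and cholesterol lists in 5 of 10 knockdown fits each and in 1 of 10 overexpression fits each, and the direction in all of them. The labels do not say whether the replicate numbers pair the livers, and 5 pairs in each experiment are too few to settle it. Deviations of same-numbered livers correlated from -0.20 to 0.35 (knockdown) and -0.11 to 0.26 (overexpression). In each experiment 1 of 5 pairs correlated best with its own number. With the number as a block, fry lost the knockdown lipogenesis list and the 3 overexpression lists and gained knockdown neutrophils; knockdown gave 3 genes and 9 lists, overexpression 544 genes and 22 lists, the difference 962 genes, the common effect 4 genes, the overlap 2 genes, the correlation -0.33 and Pklr -3.21 and 2.67. For named genes and called lists, 2153 of 2457 values under an alternative kept direction and side of the threshold, 218 fell short of it, 86 newly passed and 0 called values turned sign, while 21 signs turned with no call in either fit. The cause was not tested where a count moved, except that leaving out a library leaves fewer livers. Depth does not limit abundant genes here, but cell cycle genes at under 1 CPM in PKLR livers rest on few counts.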

Other observations

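The tests on Hcn3 and on the interferon scores were chosen after the results had been seen. The control livers of the experiments differed in level. Pklr was at 465 ± 112 CPM with shLUC and 122 ± 35.3 CPM with GFP (SD, n = 5 each), Fasn at 1376 ± 649 and 411 ± 119 CPM, Pck1 at 824 ± 179 and 2203 ± 496 CPM, the lipid droplet gene Cidec at 5.34 ± 3.12 and 41.1 ± 10.8 CPM, and the collagen gene Col1a1 at 6.94 ± 1.74 and 30.3 ± 16.1 CPM. The control vector and the experiment change together between these groups, no test was made, and the counts were deposited in separate tables.

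Hepatocyte identity genes had a median log2 fold change of -0.01 under knockdown and 0.06 under overexpression. With 1 library left out, the knockdown median ran from -0.12 (without shPKLR replicate 3) to 0.03 (without shPKLR replicate 1). The overexpression median ran from -0.0015 (without GFP replicate 1) to 0.11 (without GFP replicate 3). Of 18 glycolysis genes 1 fell in the knockdown, and 2 rose and 1 fell in the overexpression, adjusted over the list alone. Of 19 lipoprotein genes 1 rose and 3 fell adjusted over the list alone in the knockdown, and 0 in the overexpression. Over all genes, 1 of 20 bile acid genes and 2 of 24 acute phase genes rose under overexpression.

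Hcn3, an ion channel gene whose last exon overlaps that of Pklr on the other strand (GRCm38 chromosome 3, 89146074 to 89160196), moved the same way as Pklr in both experiments and was chosen after its values were seen. It was at 45.2 ± 17.5 CPM with shLUC and 7.63 ± 4.56 CPM with shPKLR (edgeR adjusted p = 0.082), and at 7.31 ± 3.44 CPM with GFP and 26.2 ± 8.83 CPM with PKLR (SD, n = 5 each; adjusted p = 0.036), and its difference between the experiments was 4.41 (SE 0.60, adjusted p = 0.00054). Reads from the Pklr end could have been counted for Hcn3 without strand. Of 288 pairs of a gene and an abundant gene overlapping on the other strand in the knockdown, 38.5% held under 0.1 of the counts that such counting would bring. This argues against counting without strand in general. For its own pair, Hcn3 held 9847 counts against 21149 from Pklr by such counting, a ratio of 0.47. Some Pklr reads among the Hcn3 counts are thus not excluded. Within groups, over 20 livers, Hcn3 followed the lipogenesis score (Pearson r = 0.79, permutation p = 0.00012; Spearman rho = 0.77, p = 2e-04; r = 0.78 without the 2 livers farthest from the median score) and Pklr (r = 0.58, permutation p = 0.029; rho = 0.60, p = 0.022; r = 0.70 without the 2 farthest; r = 0.74 in the knockdown and 0.37 in the overexpression); adjusted over these 2 relations the Pearson p-values were 0.00024 and 0.029. Regulation of Hcn3 together with lipogenic genes may account for the pattern, as a hypothesis from the same data.

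The interferon list was higher under both vectors, by 0.43 in score with shPKLR and 0.50 with PKLR. In PKLR against GFP livers the interferon score less the macrophage score was 1.06 (SE 0.35, exact permutation p = 0.024). The macrophage score itself was at -0.56, which argues against more macrophages as the source of the overexpression part. That p is not adjusted and includes GFP replicate 1, which stood apart in macrophage score, so more macrophages are not excluded. The interferon score alone had an exact permutation p of 0.079 there. Under knockdown the macrophage score was higher too, by 0.39, so more macrophages remain open for that part. An uneven draw of livers may also remain as an explanation: the exact permutation p of the summed score difference was 0.014, and 0.257 after adjustment over 35 lists. One shPKLR and 1 PKLR liver scored at or below the control mean, so the pattern is a hypothesis that more livers could settle.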
